A study of Rattus norvegicus with 37 samples.

How the data were processed

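Gene expression was measured in the left testis of male Wistar rats given 1,3-dinitrobenzene, a nitroaromatic compound with known testicular toxicity, by oral gavage once a day for 4 days. The 37 rats formed 4 groups by dose, with 8 rats given the methylcellulose vehicle alone, 10 given 0.1 mg/kg/day, 10 given 1 mg/kg/day and 9 given 4 mg/kg/day. Each rat was hybridised to its own array, with no pooling, so n is the number of rats throughout. Groups and doses were taken from the titles and treatment labels. The arrays were 1-colour Agilent rat expression arrays with 45018 spots, of which 1639 were controls. They lay on 10 slides, 7 holding 4 arrays with 1 rat of each dose and 3 holding 3 arrays, and all were scanned on 1 day.

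Per the file headers, the deposited scanner files give each spot's brightness as an intensity in linear units, made with Agilent Feature Extraction 10.7.1.1 (submitters' processing notes). The processed signal in the deposited files is this intensity after background subtraction and detrending within the array, with no normalization between arrays. The mean spot signal and the median local background, also an intensity per the file headers, were used here for a single alternative. The deposited series matrix holds log2 values made by the authors, which lay within 0.0032 of the log2 processed signal, outlier spots kept, scaled to the 75th percentile of each array minus the probe's median over the 8 control arrays (41012 probes). A further deposited table of the authors holds the same log2 values for the 4722 probes that the study called dose-responsive; the test behind that choice is not stated.

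The log2 processed signal was used here, minus the 75th percentile of the array's non-control probes, so levels are log2 relative to that percentile. Spots of 1 probe were averaged (263 of 41012 probes had several spots), and spots marked by the scanner software as non-uniform or population outliers were set to missing, which left 689 missing probe values. A probe was tested when it was well above background on at least 8 of the 37 arrays, the size of the smallest group, which kept 32947 of 41012 probes. Probes were named from a current RefSeq gene table of the rat: 11141 by accession, 5125 by symbol, 3422 by a former symbol and 1071 by gene number, while 139 kept the name in the file. The remaining 20114 probes carried no gene symbol and were counted but not named. Positions are those of the scanner files, on the rat assembly rn4.

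The 75th percentile of the processed signal ran from 896 to 1279 over the arrays. Between 70.2% and 82.7% of spots were well above background, and no spot was saturated. The median coefficient of variation of replicate spots within an array ran from 3.82% to 6.47%, and the slope of the spike-in controls from 0.938 to 0.984. Pairs of arrays correlated with Pearson r from 0.979 to 0.995 across probes, and no arrays were identical. Arrays give no counts, so the number of arrays limits the precision. The median standard error of a log2 change was 0.10 in each comparison with the controls.

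Each dose was compared with the controls, and 4 with 1 mg/kg/day, in 1 linear model over the 37 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The dose in mg/kg/day was also fitted as a number. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg procedure over the 32947 probes within each comparison. A probe was called at an adjusted p below 0.05. "Rose" and "fell" are used only of probes, genes and lists that passed. Errors of a log2 change are the standard errors of the model, and errors of a group mean are standard deviations (SD). The procedure was tested on simulated data in which 200 probes per fold change were altered among the 32947. Noise was drawn independently for each probe, so correlation between probes was not part of this test. The probes of all fold changes were altered in the same simulated data, which eases the adjusted threshold for each. At 4 mg/kg/day it recovered 33% of probes changed 1.2-fold, 73.5% of those changed 1.5-fold and 90% of those changed 2-fold, with 3.68% false calls. At 1 mg/kg/day the recovered shares were 34.5%, 76% and 93.5%, and at 0.1 mg/kg/day they were 31%, 76% and 93%.

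The 27 gene lists (cell types of the testis and its surroundings, junctions, stress responses and metabolism) held 531 gene entries, of which 475 were measured. They were tested with camera of limma at the preset inter-gene correlation of 0.01, 1 probe per gene, adjusted over the 27 lists, which compares a list with all other genes. The test was repeated with a correlation estimated from the data. Members were also counted with p adjusted over the list alone. A list score is the mean over members of the log2 level minus the control mean. Comparisons of single values used exact permutation tests, two-sided.

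Genes were named by a rule fixed in advance. Among called probes that carried a gene symbol and were well above background on every array of the group with the higher mean, it took the 12 genes with the largest rise and the 12 with the largest fall at 4 mg/kg/day, and up to 8 and 8 at each lower dose, 1 probe per gene. It added up to 4 called members of each list with the largest absolute change at 4 mg/kg/day. The comparisons, tests, gene lists, naming rule and alternative settings below, apart from those named as added, were chosen before the data were examined.

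The alternative settings were a normexp background correction (offset 50) of the mean spot signal, quantile normalization, median centring, the series matrix values, no filter, a stricter filter that kept 29736 probes, outlier spots kept, slide as a fixed or random block, the rat number as a block, an intensity trend in eBayes, array weights, a fold minimum of 1.5, only the 2 groups compared, dose rank in the trend, and leaving out each of the 37 rats. Leaving out the 5 arrays with the most albumin transcript, and normexp without control rat 2, were added after the data were seen. Rats with the same number in different groups were no more alike than others (mean r of -0.0042 over 52 pairs against 0.0007, and 2 of 37 rats correlated best with a rat of their own number), so the numbers were not treated as pairs. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and version 1.17.8 of data.table, and figures drawn with matplotlib 3.10.9. No histology, body or organ weight was used here.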

Results

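The data were 37 arrays of testis RNA, 1 per rat, from 8 control rats and from 10, 10 and 9 rats given 0.1, 1 and 4 mg/kg/day of 1,3-dinitrobenzene for 4 days. The design compares each daily dose with the vehicle and asks which genes of the testis change with dose. The 75th percentile of the processed signal was 943 to 1232 in the controls, 920 to 1215 at 0.1, 920 to 1237 at 1 and 896 to 1279 at 4 mg/kg/day. The first 3 principal components of the tested probes held 17.5%, 11.6% and 8.25% of the variance.

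At 4 mg/kg/day chemokines, a cytokine and secreted signalling proteins were among the largest rises, and a POU-domain transcription factor and a Wnt antagonist among the largest falls. Among the genes that met the naming rule, the largest rise was that of Ccl20, a chemokine, which was well above background in 9 of 9 rats and in 0 of 8 controls, at least 3.48-fold higher (adjusted p = 1.55e-14). Tfap2b, a transcription factor on chromosome 9 (probe at 18077948 to 18078007), rose by 2.02 ± 0.24 (SE, log2), from -2.99 ± 0.35 (SD, n = 8) to -0.96 ± 0.56 (SD, n = 9; adjusted p = 2.14e-08). Wnt4, a secreted signalling protein, rose by 2.14 ± 0.43, from -4.33 ± 0.52 to -2.19 ± 1.26 (adjusted p = 0.000121). Among the same genes the largest fall was that of Pou5f2, the POU-domain factor, on chromosome 2 (probe at 5622030 to 5622089), at -2.56 ± 0.20, from 0.62 ± 0.19 to -1.94 ± 0.81 (adjusted p = 3.37e-12).

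Other genes among the 12 largest rises were Tnfrsf12a (1.88 ± 0.20), a receptor of the tumour necrosis factor family, and the chemokine Cxcl1 (1.76 ± 0.25). Edn1, the precursor of the vasoconstrictor endothelin (1.49 ± 0.16), the cytokine Il1a (1.46 ± 0.32), Khdrbs2 (1.65 ± 0.16) and Prrg4 (1.61 ± 0.19) rose too. Scn3b, a sodium channel subunit, rose by 1.94 ± 0.33. Scn3b and Il1a were higher on 6 of 7 slides and the other 10 on 7 of 7, and Il1a lay above every control in 6 of 9 rats, Ly6h, Wnt4, Scn3b and Ppp1r17 in 7 and the rest in 9. Ly6h and Ppp1r17 also rose, but were well above background in 3 and 1 of 8 controls, so no size is given. Normexp background correction ended the calls of Ccl20, Ly6h, Cxcl1, Khdrbs2, Prrg4, Edn1 and Il1a and turned Ppp1r17 to -0.19, and put Wnt4 at 1.05 and Tnfrsf12a at 1.13. With that correction and without control rat 2, an alternative added after the data were seen, 0 named genes were reversed and of the 8 ended or turned only Ppp1r17 failed the test.

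The other genes among the 12 largest falls were Sfrp4, a secreted Wnt antagonist (-2.43 ± 0.16), Trim55 (-2.36 ± 0.19), Trim14 (-2.10 ± 0.17), Cd177l2 (-1.74 ± 0.09), Polr3k, a subunit of RNA polymerase III (-1.72 ± 0.12), and Ankrd34b (-1.68 ± 0.24). Ddit4l and Fam181a fell by 1.61 each, C3h15orf48 by 1.55, Abca15 by 1.51 and the olfactory receptor gene Or5h18 by 1.51 (-0.92 under normexp). Each of the 12 was lower in 9 of 9 rats than in every control, and lower on 7 of 7 slides that held both groups. Second probes of Trim55 (-1.55) and Trim14 (-2.02) also fell, while those of Sfrp4 (-0.06) and Abca15 (0.20) did not.

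In all, 13431 of 32947 tested probes changed at 4 mg/kg/day (40.8%), 7704 higher and 5727 lower, from 7044 named genes. Of these, 2054 changed at least 1.5-fold, 901 up and 1153 down. With slide as a block the count was 13471 (12664 shared). Normexp gave 7475 (3241 higher, 4234 lower; 6959 shared) and moved the median of all probes to -0.20, and median centring gave 12498 with the larger share lower (5494 higher, 7004 lower). Among 1178 genes with several called probes, 77 had probes called in both directions.

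**Figure D1:**
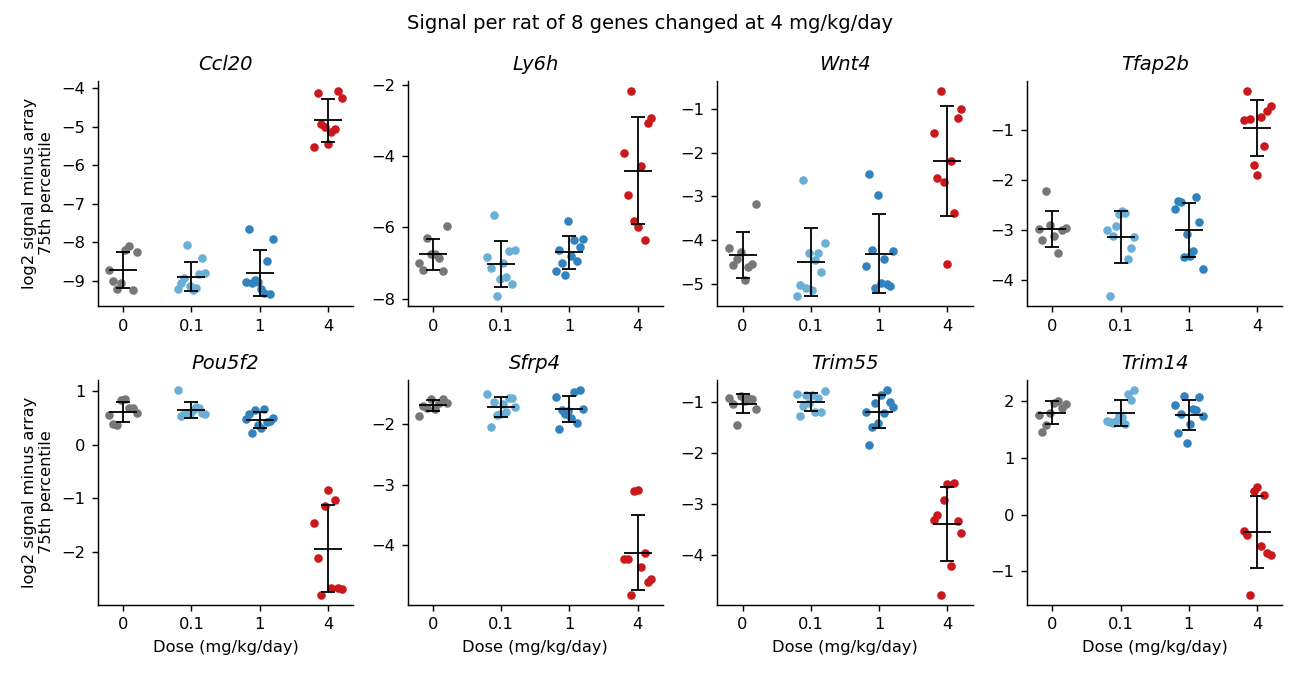
Log2 level relative to the array's 75th percentile (y axis) by daily dose (x axis) for Ccl20, Ly6h, Wnt4, Tfap2b, Pou5f2, Sfrp4, Trim55 and Trim14. Each point is 1 rat and bars are the mean and SD, with 8, 10, 10 and 9 rats. Ccl20 and Tfap2b were higher, and Pou5f2, Sfrp4, Trim55 and Trim14 lower, in 9 of 9 rats at 4 mg/kg/day than in every control.

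Many markers of Sertoli, peritubular and endothelial cells and genes of cell junctions rose at 4 mg/kg/day. None of these 4 lists passed with an estimated correlation (adjusted p = 0.365 with an estimated correlation for each), and of 100 splits of the 17 rats, the real one included, 13 gave at least the 11 lists that passed at this dose with the preset one. Of 19 measured Sertoli cell genes, 13 rose and 0 fell (6 did not pass; 13 adjusted over the list alone), among them Fshr, the receptor of follicle-stimulating hormone (0.60 ± 0.08), the tight junction gene Cldn11 (0.54 ± 0.09), Kitlg, the ligand of the germ cell receptor Kit (0.50 ± 0.09), and Dhh (0.42 ± 0.09; its second probe was at 0.08). Of 9 peritubular and smooth muscle genes, 7 rose and 0 fell (7 adjusted over the list alone), with Tagln at 0.61 ± 0.09, Cnn1 at 0.59 ± 0.13, Lmod1 at 0.52 ± 0.14 (well above background in 6 of 8 controls) and Tpm2 at 0.41 ± 0.09. Of 26 genes of the blood-testis barrier and junctions, 17 rose and 2 fell (17 and 2 adjusted over the list alone), with Cdh2 at 0.68 ± 0.08, Itgb1 at 0.50 ± 0.10 and Ocln at 0.48 ± 0.08. Of 12 endothelial genes, 6 rose and 0 fell (6 adjusted over the list alone), with Tek at 0.69 ± 0.11, Tie1 at 0.40 ± 0.12 (well above background in 7 of 8 controls; second probe 0.14, not past the test), Kdr at 0.36 ± 0.10 and Esam at 0.36 ± 0.07.

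As lists, these 4 passed the camera test for Sertoli cells (median 0.31, adjusted p = 0.000931), peritubular cells (0.41, adjusted p = 0.00697), junctions (0.28, adjusted p = 0.00154) and endothelial cells (0.25, adjusted p = 0.0471). None of the 4 passed with an estimated correlation (adjusted p = 0.365 with an estimated correlation for each). With slide as a block the values were 0.00059, 0.00853, 0.00134 and 0.0417, and each list score was higher on 7 of 7 slides. The score was above every control in 8 of 9 rats for Sertoli cells and in 9 of 9 for peritubular cells. Under normexp the peritubular median was 0.21 (0.31 without control rat 2). The endothelial median turned to -0.08, or 0.13 without control rat 2 (0.12 and 0.16 relative to all probes). Normexp also ended the calls of Fshr, Dhh and Esam, put Cdh2 at 0.35, and turned Tek (-0.12), Tie1 (-0.31), Cnn1 (-0.01) and Lmod1 (-0.30). Without control rat 2 it did not reverse these genes. The endothelial call was also lost by averaging the probes of a gene, by quantile normalization and by a block for rat number (adjusted p = 0.0609; 0.0251 to 0.111 over 7 alternatives).

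Markers of other somatic cells did not pass as lists. Of 17 Leydig cell and steroid synthesis genes, 2 rose and 3 fell (median 0.17, adjusted p = 0.823; 2 and 3 adjusted over the list alone). Srd5a1, which reduces testosterone, fell by 0.73 ± 0.11 with its second probe at -0.15, Hsd17b3, which makes testosterone, rose by 0.61 ± 0.16, and Tspo rose by 0.24 ± 0.09. The Hsd3b2 probe fell by 0.50 ± 0.19 while a second probe was at 0.37, and the scanner files place the first on chromosome M. Hsd17b3 was higher on 5 of 7 slides and Hsd3b2 lower on 4 of 7. Normexp ended the call of Hsd3b2, as did leaving out the 5 rats with the most albumin transcript, an alternative added after the data were seen, which also ended that of Tspo. Of 17 macrophage and leukocyte genes, 4 rose and 0 fell (median 0.11, adjusted p = 0.244), and 1 rose adjusted over the list alone. These 4 were Itgam, well above background in 4 of 8 controls and so given no size, Cd163 (0.53 ± 0.11), Cd14 (0.25 ± 0.10; second probe 0.36, not past the test) and Mrc1 (0.24 ± 0.09), and normexp turned Itgam (-0.27), Cd163 (-0.00) and Cd14 (-0.01) and ended the call of Mrc1. Without control rat 2 normexp did not reverse Itgam, Cd163 or Cd14. Slide as a block ended the call of Itgam, quantile normalization that of Cd14, and leaving out the same 5 rats that of Mrc1.

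Tissue next to or within the testis was followed by 3 lists, none of which passed. Blood cell genes held 3 rises and 0 falls among 10 (median 0.20, adjusted p = 0.380; 3 adjusted over the list alone), Hbb (0.73 ± 0.22), Hbb-b1 (0.72 ± 0.19) and Alas2 (0.54 ± 0.10). Fat cell genes held 2 rises among 8 (median 0.01, adjusted p = 0.775; 1 adjusted over the list alone), Fabp4 (0.58 ± 0.18; well above background in 5 of 8 controls) and Adipoq (0.24 ± 0.10). Epididymis genes held 1 rise and 1 fall among 9 (median 0.14, adjusted p = 0.989; 1 and 1 adjusted over the list alone), and Crisp3 fell by 0.51 ± 0.10. Crisp3 was not itself a symbol of the list as fixed, and entered it because a listed symbol is a synonym of that gene. The medians of the blood (-0.31), fat (-0.29) and epididymis (-0.39) lists were negative under normexp, and that of fat (-0.05) under median centring. Normexp also ended the calls of Hbb and Adipoq and turned Fabp4 (-0.32), and slide as a block and leaving out the same 5 rats each ended that of Adipoq. Without control rat 2 normexp gave medians of -0.06, -0.04 and -0.07 for blood, fat and epididymis, and did not reverse Fabp4.

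Germ cell genes moved both ways at 4 mg/kg/day, and none of their 4 lists passed. Of 27 spermatocyte and meiosis genes, 12 fell and 6 rose (13 and 7 adjusted over the list alone), among them falls of Spo11, which makes the meiotic DNA breaks (-0.98 ± 0.08), Sycp2 of the synaptonemal complex (-0.66 ± 0.06) and Tex14 of the intercellular bridges (-0.52 ± 0.05), and a rise of Syce2, also of the synaptonemal complex (0.48 ± 0.07). The list had a median of -0.07 and an adjusted p of 0.0648 (0.0957 with slide as a block; 0.365 with an estimated correlation), though its score lay below every control in 9 of 9 rats and was lower on 7 of 7 slides. Relative to all probes its median was 0.14 under normexp and -0.05 with that correction without control rat 2. It passed with the mean of a gene's probes (adjusted p = 0.0449) and with median centring (adjusted p = 0.0381), within a range of 0.0381 to 0.197 over 7 alternatives.

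Of 14 spermatogonium genes, 6 rose and 1 fell (median 0.17, adjusted p = 0.161; 6 and 1 adjusted over the list alone), with rises of the cyclin Ccnd2 (0.75 ± 0.11), Dazl (0.40 ± 0.09), Etv5 (0.35 ± 0.06) and Sohlh1 (0.28 ± 0.07). Of 18 round spermatid genes, 10 rose and 4 fell (median 0.21, adjusted p = 0.380; 10 and 4 adjusted over the list alone). Tbpl1, a spermatid transcription factor, fell by 0.60 ± 0.06, Zpbp2 by 0.28 ± 0.06 and the sperm calcium channel subunit Catsper2 by 0.27 ± 0.06, and Sun5 rose by 0.27 ± 0.09. Of 19 elongating spermatid genes, 2 rose and 0 fell (median 0.02, adjusted p = 0.601, and -0.04 with median centring; 2 adjusted over the list alone), the sperm tail genes Cabyr (0.35 ± 0.05) and Akap4 (0.21 ± 0.06). Normexp ended the calls of Etv5 and Catsper2 and put Ccnd2 at 0.47, and leaving out the same 5 rats that of Sun5.

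Many genes of detoxification, inflammation and early response rose at 4 mg/kg/day, and many of oxidative phosphorylation fell. The 7 lists described here and next passed at the preset correlation, where 13 of 100 splits gave at least the 11 lists that passed at this dose, and none passed with an estimated one (adjusted p = 0.365 with an estimated correlation for each). Of 22 NRF2 target and glutathione genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with Gclc, which limits glutathione synthesis (0.75 ± 0.08), Hmox1, haem oxygenase (0.66 ± 0.09), Gstp1 (0.61 ± 0.12) and Ephx1 (0.48 ± 0.10). Of 16 xenobiotic metabolism genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with Akr7a3 (0.61 ± 0.11), Akr1b8 (0.49 ± 0.10), Nat1 (0.48 ± 0.09) and Aox1 (0.44 ± 0.10). Of 19 cytokine and chemokine genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone), led by Cxcl1, Il1a, Cxcl10 (1.24 ± 0.17) and Il1b (0.66 ± 0.19). Of 16 immediate early genes, 13 rose and 0 fell (13 adjusted over the list alone), with Ccn1 (0.81 ± 0.16; second probe 0.39, not past the test), Egr1 (0.72 ± 0.11), Fos (0.60 ± 0.17) and Ier3 (0.58 ± 0.11).

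Of 20 genes of oxidative phosphorylation, 12 fell and 0 rose (15 adjusted over the list alone). Atp5f1c, a subunit of ATP synthase, fell by 0.72 ± 0.06, Cyct, the testis form of cytochrome c, by 0.71 ± 0.08, Cox7a2 by 0.38 ± 0.07 and Sdha by 0.35 ± 0.05. Of 16 p53 target genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone), with rises of the pro-apoptotic Bbc3 (0.91 ± 0.14), Plk3 (0.56 ± 0.09) and Plk2 (0.54 ± 0.08) and a fall of Tp53inp1 (-0.60 ± 0.06). Of 18 extracellular matrix genes, 11 rose and 0 fell (11 adjusted over the list alone), with the protease Mmp14 (0.53 ± 0.08), fibronectin Fn1 (0.48 ± 0.12), Timp1 (0.46 ± 0.14) and Lum (0.46 ± 0.16; well above background in 6 of 8 controls).

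As lists, these 7 passed the camera test, with medians and adjusted p of 0.22 and 0.00697 for NRF2 targets, 0.37 and 0.00697 for xenobiotic metabolism, 0.34 and 0.00697 for cytokines, 0.44 and 0.00104 for immediate early genes, -0.22 and 0.000217 for oxidative phosphorylation, 0.21 and 0.0439 for p53 targets, and 0.33 and 0.0294 for extracellular matrix. None passed with an estimated correlation (adjusted p = 0.365 with an estimated correlation for each). With slide as a block 6 of the 7 passed (adjusted p from 0.000248 to 0.0146) and p53 targets did not (0.0615), a call also lost by averaging the probes of a gene and by quantile normalization (0.0215 to 0.0615 over 7 alternatives). Each list moved the same way on 7 of 7 slides apart from extracellular matrix, on 6 of 7, and the scores of immediate early genes and of oxidative phosphorylation lay beyond every control in 9 of 9 rats. Under normexp the median of immediate early genes turned to -0.01 (0.19 relative to all probes), and those of cytokines and extracellular matrix shrank to 0.005 and 0.05. Without control rat 2 these medians were 0.19, 0.24 and 0.18. The median of oxidative phosphorylation relative to all probes turned to 0.09 under normexp (-0.15 without control rat 2). Normexp also ended the calls of Gclc, Nat1, Egr1, Ier3, Plk3 and Fn1 and put Cxcl10 at 0.67, and it turned Il1b (-0.06), Ccn1 (-0.03), Fos (-0.14) and Lum (-0.32), and quantile normalization ended that of Lum. Without control rat 2 normexp did not reverse Il1b, Ccn1, Fos or Lum.

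Another 7 lists of stress, structure and metabolism did not pass at 4 mg/kg/day. Of 28 apoptosis genes, 14 rose and 5 fell (median 0.27, adjusted p = 0.328; 14 and 5 adjusted over the list alone), with rises of Casp8 (0.75 ± 0.20) and Bid (0.67 ± 0.13), both well above background in 5 of 8 controls, and of Bik (0.57 ± 0.14) and Xiap (0.56 ± 0.11), a caspase inhibitor. Of 16 antioxidant genes, 8 rose and 2 fell (median 0.20, adjusted p = 0.298; 8 and 2 adjusted over the list alone), with catalase Cat (0.42 ± 0.11), Txn1 (0.39 ± 0.10), Gpx1 (0.37 ± 0.11) and Selenop (0.35 ± 0.11). Of 22 unfolded protein and stress response genes, 8 rose and 3 fell (median 0.17, adjusted p = 0.369; 8 and 3 adjusted over the list alone), with Ppp1r15a (0.61 ± 0.10), Psat1 (0.48 ± 0.13; well above background in 6 of 8 controls), Mthfd2 (0.43 ± 0.10) and a fall of Ddit3 (-0.36 ± 0.07). Of 14 heat shock genes, 6 rose and 3 fell (median 0.15, adjusted p = 0.658; 6 and 3 adjusted over the list alone), with Hspa4 (0.46 ± 0.06; second probe -0.04), Cryab (0.43 ± 0.13), Hspa4l (-0.41 ± 0.07) and Dnajb1 (-0.39 ± 0.04).

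Of 22 glycolysis genes, 10 rose and 3 fell (median 0.16, adjusted p = 0.244; 11 and 3 adjusted over the list alone), with falls of the glucose transporter Slc2a3 (-0.67 ± 0.10) and Pfkp (-0.41 ± 0.05) and rises of Hk2 (0.52 ± 0.09) and Pgk1 (0.30 ± 0.07). Of 23 cholesterol synthesis genes, 9 rose and 7 fell (median 0.04, adjusted p = 0.823; 10 and 7 adjusted over the list alone), with Mvd (-0.52 ± 0.06), Stard4 (0.44 ± 0.06), Sc5d (-0.36 ± 0.07) and Nsdhl (0.36 ± 0.08). Of 18 cytoskeleton genes, 6 rose and 3 fell (median -0.00 but mean 0.05 and test upward, adjusted p = 0.989; 6 and 3 adjusted over the list alone), with Flna (0.53 ± 0.09), Stmn1 (-0.52 ± 0.06), Vim (0.36 ± 0.09) and Tubb3 (0.32 ± 0.09). The cholesterol median was -0.02 with median centring and -0.09 under normexp, that of cytoskeleton genes 0.03 with quantile normalization and 0.05 under normexp, and that of apoptosis genes -0.21 under normexp. Normexp turned Casp8 (-0.32), Bid (-0.32), Xiap (-0.18), Cat (-0.02), Psat1 (-0.28), Stard4 (-0.08), Nsdhl (-0.09) and Hk2 (-0.21), ended the call of Selenop and put Ppp1r15a at 0.35, and leaving out the same 5 rats ended that of Tubb3. With normexp and without control rat 2 the cholesterol, cytoskeleton and apoptosis medians were 0.10, 0.05 and 0.05, and 0 named genes were reversed.

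**Figure D2:**
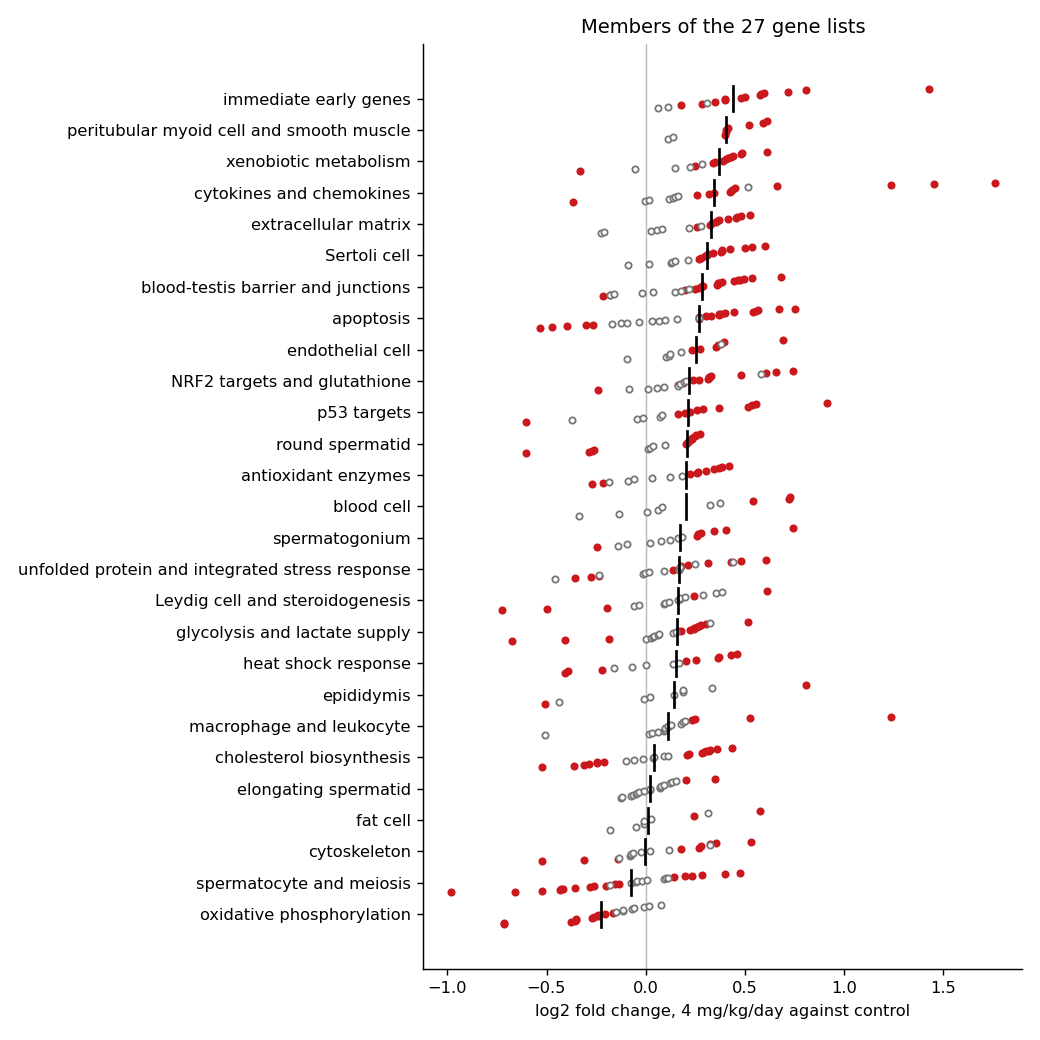
Log2 change at 4 mg/kg/day against control (x axis) for the measured members of each of the 27 gene lists (y axis). Filled red points passed the test at an adjusted p below 0.05, open points did not, and black bars are list medians. Oxidative phosphorylation holds 12 falls and 0 rises, while Sertoli cell genes hold 13 rises and 0 falls. Under normexp the medians of the endothelial, immediate early, apoptosis, blood, fat, epididymis and cholesterol lists are negative, and that of oxidative phosphorylation relative to all probes is 0.09.

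**Figure D3:**
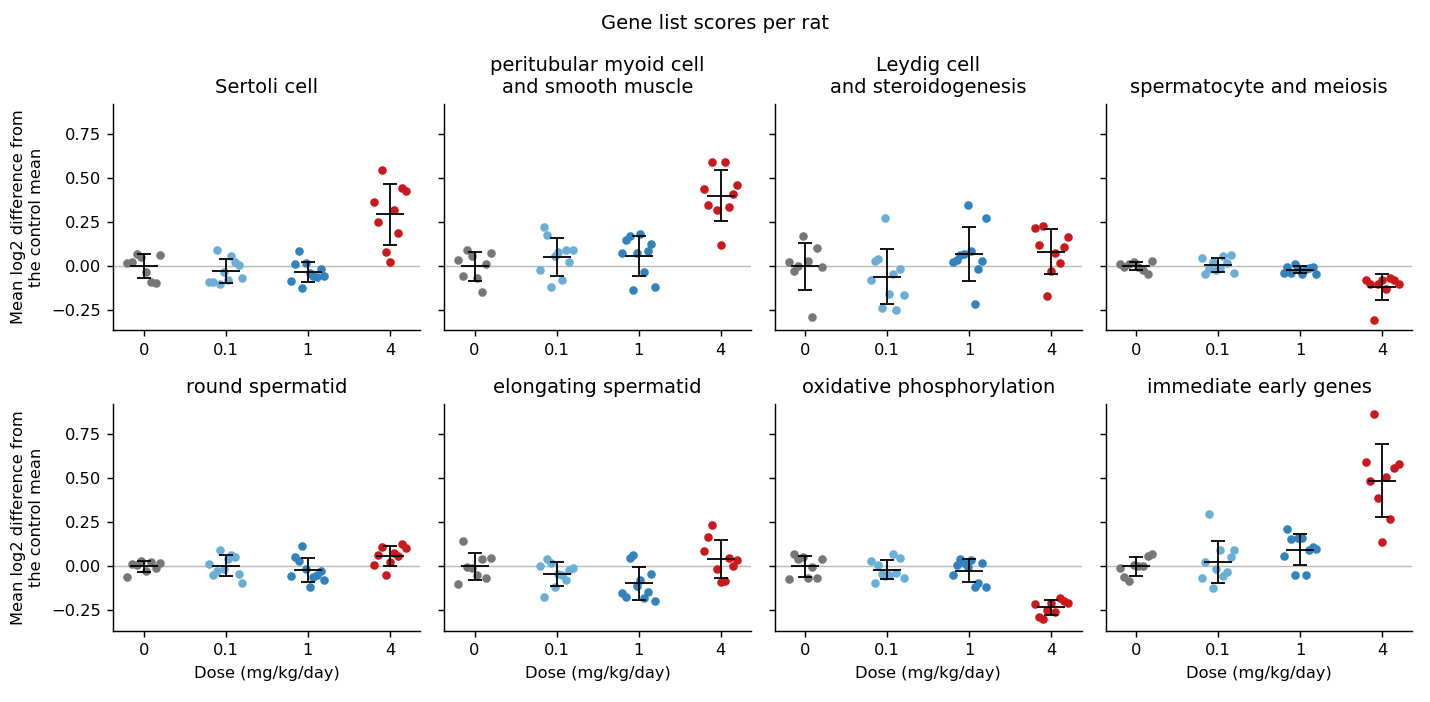
Mean log2 level of a list relative to the control mean (y axis) by daily dose (x axis) for Sertoli cell, peritubular, Leydig cell, spermatocyte, round spermatid, elongating spermatid, oxidative phosphorylation and immediate early genes. Each point is 1 rat and bars are the mean and SD, with 8, 10, 10 and 9 rats. Peritubular and immediate early scores lie above every control in 9 of 9 rats at 4 mg/kg/day, and the median of immediate early genes is -0.01 under normexp.

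At 1 mg/kg/day no single gene passed the test, and elongating spermatid genes were the single list that did. Their 19 members had a median change of -0.10 (adjusted p = 8.04e-08, 1.17e-07 with slide as a block), lost with an estimated correlation (adjusted p = 0.964 with an estimated correlation). Of the members 0 passed, also adjusted over the list alone, and the score lay below every control in 6 of 10 rats. Within slides it was lower on 5 of 8 and higher on 3. The median shrank to -0.03 with quantile normalization and to -0.00 under normexp, where it was 0.17 relative to all probes (-0.02 without control rat 2). With limma 0 of 32947 probes were called, with 1516 at an unadjusted p below 0.05 (4.60%) and a lowest adjusted p of 0.999. The shares of simulated changes recovered at this dose were 93.5% at 2-fold, 76% at 1.5-fold and 34.5% at 1.2-fold, so small changes could be missed.

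At 0.1 mg/kg/day no gene and no list passed. The nearest gene was Tinagl1, at 0.88 ± 0.16 (adjusted p = 0.0718, limma), and the nearest list was that of endothelial genes (adjusted p = 0.108). Tinagl1 passed when control rat 1 (adjusted p = 0.0418), 0.1 mg/kg/day rat 7 (0.0251) or rat 8 (0.0186), or 4 mg/kg/day rat 3 (0.0294) was left out, with changes from 0.74 to 0.94. With limma 0 probes were called, with 924 at an unadjusted p below 0.05 (2.81%), and 0 of 475 list members passed over all probes or adjusted over the list alone. The shares of simulated changes recovered were 93% at 2-fold, 76% at 1.5-fold and 31% at 1.2-fold. As at 1 mg/kg/day, they may be too high for a change in few probes.

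The 12 genes with the largest rise and the 12 with the largest fall at 4 mg/kg/day also differed between 4 and 1 mg/kg/day, though they were chosen on the same 9 rats at 4 mg/kg/day. Tfap2b was higher at 4 than at 1 mg/kg/day by 2.04 (adjusted p = 5.18e-09). Pou5f2 was lower by 2.40 (-2.40, adjusted p = 3.17e-12) and Cd177l2 by 1.73 (-1.73, adjusted p = 3.69e-17). Sertoli cell genes held 15 rises and 0 falls (17 and 0 adjusted over the list alone; median 0.35, adjusted p = 0.000164) and genes of oxidative phosphorylation 13 falls and 0 rises (13 adjusted over the list alone; median -0.17, adjusted p = 0.000166). Neither passed with an estimated correlation (adjusted p = 0.443 with an estimated correlation for both).

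Between 4 and 1 mg/kg/day 13298 probes differed, 7617 higher and 5681 lower at 4, and 1720 of them at least 1.5-fold (599 higher, 1121 lower). Of these probes 11306 also differed between 4 mg/kg/day and control, each in the same direction (6312 higher, 4994 lower, against 1781 and 987.5 for unrelated calls), but both comparisons use the same 9 rats at 4 mg/kg/day. With slide as a block the count was 13373. The larger share was lower with median centring (5218 higher, 6907 lower) and with normexp, which gave 6979 (3407 higher, 3572 lower). A further 9 lists passed, all upward: elongating spermatid genes (8 of 19 members, adjusted p = 0.0253), peritubular cells (0.0188), junctions (0.00138), NRF2 targets (0.0111), p53 targets (0.0437, and 0.0556 with slide as a block), immediate early genes (0.00649), xenobiotic metabolism (0.0136), extracellular matrix (0.0394) and cytokines (0.0186). These 9 were also lost, with adjusted p = 0.652 for elongating spermatid genes and adjusted p from 0.443 to 0.474 for the rest with an estimated correlation. Elongating spermatid genes had not passed at 4 mg/kg/day against control (median 0.02, camera adjusted p = 0.601), and their median at 1 mg/kg/day was -0.10. Their median difference between 4 and 1 mg/kg/day was 0.13, and 0.06 with quantile normalization. Endothelial genes did not pass here (adjusted p = 0.107). Over the lists, 274 of 475 members passed, and 291 adjusted over the list alone, against 273 and 277 for 4 mg/kg/day with control.

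With dose as a number, 15805 probes had a slope that passed, 9400 upward and 6405 downward. Of these, 13069 had also changed at 4 mg/kg/day, each in the same direction, but both fits use the same 9 rats at 4 mg/kg/day. With slide as a block the count was 15844. The larger share was downward with median centring (6612 upward, 8042 downward) and with normexp, which gave 8587 (4220 upward, 4367 downward). No probe passed at either lower dose alone with limma (924 and 1516 at an unadjusted p below 0.05).

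The 2054 probes changed at least 1.5-fold at 4 mg/kg/day were averaged per rat, with falls counted as positive, as a response score. It was 0.00 ± 0.05 (SD, n = 8) in controls, 0.08 ± 0.05 (n = 10) at 0.1, 0.10 ± 0.03 (n = 10) at 1 and 0.82 ± 0.19 (n = 9) at 4 mg/kg/day, where single rats ran from 0.52 to 1.15. Within slides it was higher than the control on 6 of 8, 8 of 8 and 7 of 7 slides. The probes were chosen on these arrays with the same controls, so the scores of the lower doses are not independent of that choice.

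**Figure D4:**
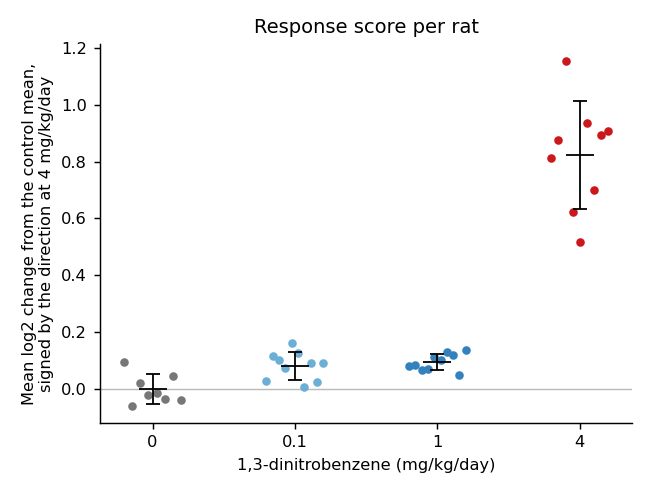
Response score in log2 (y axis), the mean change of the 2054 probes changed at least 1.5-fold at 4 mg/kg/day with falls counted as positive, by daily dose (x axis). Each point is 1 rat and bars are the mean and SD. The 9 rats at 4 mg/kg/day lie between 0.52 and 1.15, above all others.

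Across 32947 probes, which are not independent replicates, the changes at 1 and at 4 mg/kg/day had a Pearson r of 0.34, and 0 calls were shared. Both use the same controls: simulated unchanged groups that shared their controls gave a median r of 0.53, from 0.15 to 0.73. The simulated groups held no change, while 13431 probes changed at 4 mg/kg/day, so these r cannot be compared directly. The covariance of the changes at 1 and at 4 mg/kg/day was 0.0173 (simulated 0.0139, from 0.0029 to 0.0288). With the controls split into 2 sets of 4 the mean r was 0.01. The r of 0.1 with 4 mg/kg/day was 0.31 (simulated median 0.56, with the same limit, split controls -0.01). That of 0.1 with 1 mg/kg/day was 0.58 (0.56 and -0.10). The covariance of 0.1 with 4 mg/kg/day was 0.0159 (simulated 0.014, from 0.0035 to 0.0274). That of 0.1 with 1 mg/kg/day was 0.0128 (simulated 0.014, from 0.0042 to 0.0295). Each covariance lay within its simulated range, so no similarity beyond shared controls was shown.

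Of the 4722 probes that the study lists as dose-responsive, 4722 passed both the F test over the 3 doses and the test at 4 mg/kg/day here, with 2111 higher and 2611 lower. The F test passed 13196 probes in all. The study chose that list on these arrays, so its direction is not independent evidence.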

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

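The tests of dose and slide for the liver transcripts, the tests of the Sertoli cell markers and the splits of the samples at 0.1 and 1 mg/kg/day were chosen after the result was seen.

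Sertoli and peritubular scores were higher at 4 mg/kg/day, by 0.29 and 0.40, though neither list passed with an estimated correlation (adjusted p = 0.365 with an estimated correlation for both). A lower share of germ cells would raise the markers of every somatic type alike. The Sertoli score did not separate from those of macrophages (0.11, 95% interval -0.07 to 0.29, exact permutation p = 0.27, adjusted p = 0.324) or endothelium (0.03, interval -0.08 to 0.15, p = 0.607, adjusted p = 0.607). These intervals are too wide to show a like rise. The Sertoli score rose by more than that of elongating spermatids (0.25, exact permutation p = 0.000782, adjusted p = 0.00272), whose list did not pass, so fewer of these cells were not shown. It rose by 0.21 more than the Leydig score (95% interval 0.11 to 0.31, exact permutation p = 0.00148, adjusted p = 0.00296 over 6 comparisons). By the rule of this test an interval above 0 goes against a lower share. But the Leydig genes went both ways (2 rose, 3 fell, 1 of these by the Hsd3b2 probe of doubtful position), as did the round spermatid genes (10 rose, 4 fell; 0.23, exact permutation p = 0.000905, adjusted p = 0.00272), so neither mean decides. The Sertoli score rose by less than the peritubular score (-0.11, exact permutation p = 0.0153, adjusted p = 0.0229), so these 2 did not rise alike. Relative to all probes the lowest of the medians of both lists was 0.32 with quantile normalization and normexp, and 0.27 with median centring. That measure removes a shift common to all probes, so it cannot test the scaling of the arrays. Without that step the Sertoli medians were 0.25, 0.34 and 0.28 with median centring, quantile normalization and normexp. The peritubular medians were 0.35, 0.42 and 0.21, so both lists stayed above 0 under each scaling tried. A lower share of germ cells and a change within Sertoli and peritubular cells both stay open.

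Transcripts of the liver differed by rat: Alb stood at 2.88 in control rat 2, 2.76 and 2.71 in 4 mg/kg/day rats 8 and 9, 1.82 in 0.1 mg/kg/day rat 8 and 1.59 in 1 mg/kg/day rat 3, against 0.71 in the next rat. Of 30 liver genes set aside for a test, 29 were measured and 22 were above background on every array, so testis shows them too; the median Pearson r of these 22 with Alb over the 37 rats was 0.58, between the bounds of 0.7 and 0.3 set beforehand, and that of all 29 was 0.61, with 13 members above 0.7, against -0.06 for kidney and -0.08 for seminal vesicle and prostate genes. The liver score followed Alb with r = 0.88 and rho = 0.83 (permutation p = 1e-05 for both, the smallest that 100000 permutations give), r = 0.83 without the 2 farthest rats and 0.64 without the 5 above, where the median r of the members fell to 0.27 and 3 of 29 exceeded 0.5, so RNA of liver in some samples may be the source but stays open. No effect of dose was shown, since the liver score differed by 0.10 between 4 mg/kg/day and control (interval -0.25 to 0.44, exact permutation p = 0.634). The interval is too wide to exclude such an effect, so dose stays open too. Slide was argued against, since it held 16.6% of the variance against a permuted median of 23.5% (permutation p = 0.803). Without these 5 rats, a choice made after the data were seen, 11340 probes changed at 4 mg/kg/day (10996 shared), 11497 differed between 4 and 1 mg/kg/day, 13978 had a dose trend and 11 lists passed.

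Chance was unlikely for 3 of the counts by other splits of the same rats, drawn without regard to slide. The smallest share that 100 splits can give is 1 of 100. Of 100 splits of the 17 rats given 4 mg/kg/day or vehicle, the real one included, 1 gave as many probes (13431, highest other 2939), and of 100 splits for 4 against 1 mg/kg/day 1 did (13298, highest other 3248). Of 100 assignments of the doses to the 37 rats, 1 gave as many probes with a trend (15805, highest other 1). At 1 and 0.1 mg/kg/day the real counts were 0, which all 100 splits reach whatever the data, so the splits test nothing there (highest other 6 and 1). Chance cannot be excluded for the number of gene lists: 13 of 100 splits gave at least the real 11 (highest other 15, and 81 splits gave at least 1).

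Among 172 groups of values examined for a rat far from the rest, 13 held such a rat (7.56%), where chance gives about 1 in 20, or 8.6. In 0.1 mg/kg/day rat 3 the scores of 4 lists were high, those of macrophages (0.53, next 0.09), cytokines (0.44, next -0.00), immediate early genes (0.30, next 0.09) and apoptosis (0.20, next 0.02). In the 4 mg/kg/day group the spermatocyte score was low in rat 3 (-0.31, next -0.13), the endothelial score in rat 4 (-0.0079, next 0.18) and the spike-in slope in rat 8 (0.938, next 0.953). In the controls the Leydig score was low in rat 6 (-0.29, next -0.03) and the heat shock score high in rat 8 (0.0919, next 0.0108). Also in the controls Wnt4 was high in rat 8 (-3.16, next -4.18), Tfap2b in rat 3 (-2.23, next -2.91) and Il1a in rat 1 (-2.41, next -3.36), and Trim55 was low in rat 3 (-1.44, next -1.14).

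Of 8065 probes too dim to be tested, 16 were well above background in at least 5 of 9 rats at 4 mg/kg/day and in 0 of 8 controls, and 0 showed the opposite. The share of spots well above background was 74.9% to 82.7% at 4 mg/kg/day and 70.8% to 80.1% in controls. A difference between the arrays was not separated from a change of these genes. The 6 with a gene symbol, named after their values were seen, were Atp1b4, Cyp11b1, Reg3b and Rnf213 in 5 rats each and Hoxd1 and Zfand5 in 6 rats each.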

How the results depend on the processing

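Normexp without control rat 2 and the fits without the 5 rats rich in albumin transcript were chosen after the result was seen. Of 16 alternatives tried for the counts at 4 mg/kg/day and for 4 against 1 mg/kg/day, 14 stayed within 1.5 times the reported count (9317 to 13746 and 10784 to 13551), as did 14 of 15 for the dose trend (12224 to 15990). At 0.1 and 1 mg/kg/day 16 of 16 gave 0. A fold minimum of 1.5 left 2054 and 1720 probes, because it asks for more. Normexp gave 7475 at 4 mg/kg/day, 6979 for 4 against 1 and 8587 for the trend. Dose rank gave 12421. Control rat 2 carries part of this, since without it normexp gave 9317, 10784 and 12224, and the median of all probes at 4 mg/kg/day lay at -0.03 in place of -0.20 (-0.02 in place of -0.15 at 0.1, -0.05 in place of -0.17 at 1). Median centring moved the direction to 5218 higher and 6907 lower for 4 against 1 and to 6612 higher and 8042 lower for the trend. Leaving out each of the 37 rats gave 12471 to 13788 probes at 4 mg/kg/day, 12110 to 13727 for 4 against 1, 14509 to 15964 for the trend, 0 at 1 and 0 to 1 at 0.1 mg/kg/day. Gene lists passed in 9 to 12 cases under 7 alternatives and in 0 with an estimated correlation. Lists that had not passed reversed without passing: epididymis with the mean of probes (adjusted p = 0.966), quantile normalization (0.740) and no filter (0.874), cholesterol synthesis with the mean of probes (0.576), and cytoskeleton with median centring (0.951) and the rat number as a block (0.992). Splitting the controls took the r of 1 with 4 mg/kg/day to 0.0088, because the 2 comparisons then share no control, and quantile normalization gave 0.35.

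Of 121 named genes, normexp left 77 past the threshold in the same direction, ended 23 calls and reversed 21: Ppp1r17 (-0.19), Itgam (-0.27), Cd163 (-0.0043), Cd14 (-0.0073), Tek (-0.12), Tie1 (-0.31), Cnn1 (-0.0143), Lmod1 (-0.30), Fabp4 (-0.32), Cat (-0.0163), Casp8 (-0.32), Bid (-0.32), Xiap (-0.18), Psat1 (-0.28), Ccn1 (-0.0341), Fos (-0.14), Stard4 (-0.0816), Nsdhl (-0.0877), Hk2 (-0.21), Lum (-0.32) and Il1b (-0.0618). Without control rat 2 it reversed 0 and ended 24 calls. Quantile normalization and slide as a block each ended 2 calls, the rat number as a block 0, and leaving out the 5 rats 6 (Hsd3b2, Tspo, Sun5, Mrc1, Adipoq and Tubb3). For every other result that moved, the cause was not tested. All arrays were scanned on 1 day, so a block for scan date was not run. Signal over background limits the dim genes: 8065 probes were not tested.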

Other observations

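The tests of the histocompatibility classes and of probes chosen on separate controls were chosen after the result was seen.

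Genes of the X chromosome rose as a group at 4 mg/kg/day. The 1151 tested X-linked probes had a median change of 0.25 against 0.03 for the autosomes, the highest of 21 chromosomes, followed by chromosome 17 at 0.08. Of the 636 X-linked probes that passed, 601 were higher (94.5%), against 55.0% higher among the autosomal probes that passed. The gene lists above were not split by chromosome, so a rise of an X-linked member was not separated from this shift. Named after their values were seen, Wwc3 (1.27), Trpc5 (1.02), Nhs (0.96), Msn (0.92), Mcf2 (0.79), Suv39h1 (0.78), Magee1 (0.78) and Armcx3 (0.74) rose, while Serpina7 (-0.79), Kpna1-ps10 (-0.53), Cenpwl1 (-0.45) and Da2-19 (-0.44) fell. Per rat, the X median minus the autosomal median was 0.22 ± 0.08 (SD, n = 9) at 4 mg/kg/day and 0.00 ± 0.02 (n = 8) in controls (exact permutation p = 0.000123, adjusted p = 0.000369 over 3 doses), above every control in 9 of 9 rats and higher on 7 of 7 slides (0.13 to 0.34). At 0.1 and 1 mg/kg/day it was 0.01 ± 0.03 and -0.01 ± 0.03 (exact permutation p = 0.721 and 0.462).

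The X chromosome is silenced in meiotic spermatocytes, so fewer such cells, as a hypothesis, could raise it against the autosomes, and the difference of 0.22 over probes met the bound set beforehand. A level effect was argued against, since 0 of 10000 autosomal sets matched on mean signal reached the X median (highest 0.0820), and the difference was 0.22 and 0.15 with quantile normalization and normexp. The spermatocyte list did not itself pass (adjusted p = 0.0648), so a failure of silencing within the cells or a larger share of somatic cells, in which the X is active, stays open and was not tested.

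The histocompatibility gene RT1-Bb (chromosome 20, probe at 4732962 to 4733021) took 3 separate ranges of level over the 37 rats: -0.21 to 0.64 in 15 rats, 1.86 to 2.09 in 13 and 2.50 to 2.92 in 9. The lowest range held 6, 2, 3 and 4 rats of the control, 0.1, 1 and 4 mg/kg/day groups, the middle 0, 5, 6 and 2, and the highest 2, 3, 1 and 3, and RT1-Bb did not pass at 4 mg/kg/day (0.64, adjusted p = 0.358). Haplotypes of the histocompatibility region that differ between the rats are a candidate explanation: of the 20 probes that followed RT1-Bb most closely, 14 lie on chromosome 20, which holds 2.64% of the probes. Of the 20, 9 are probes of RT1 genes, of which those of RT1-CE16 and RT1-CE12 lie on 20_random in the scanner files and are not among the 14. A further 7 on chromosome 20 are not named so, among them Pfdn6 (r = 0.88) and Gpsm3 (r = -0.86), named after their values were seen. Sequence variants under the probes would show the same pattern and were not tested.

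A response at the lower doses was looked for with probes chosen on some controls and scored against the others. With probes chosen on the odd-numbered controls (7031 probes), the score of the 10 rats at 1 mg/kg/day was 0.04 above the 4 other controls (exact permutation p = 0.002), and with the even-numbered controls (10257 probes) it was -0.0027 (p = 0.897). At 0.1 mg/kg/day the values were 0.03 (exact permutation p = 0.119) and -0.01 (p = 0.653), against 0.49 and 0.38 at 4 mg/kg/day. The rats at 4 mg/kg/day were not held out, so their values are not independent of the choice of probes. At 1 mg/kg/day a higher score was thus seen with probes chosen on the odd-numbered controls, and no difference with the even-numbered.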
